A study of Arabidopsis thaliana with 36 samples.

How the data were processed

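Polyadenylated transcripts were measured by RNA sequencing in rosette leaves 9 to 12 of Arabidopsis thaliana plants grown on soil for 5 weeks in 8 h of light and 16 h of dark. The 36 libraries covered 3 genotypes in 6 conditions with 2 libraries each. The genotypes were the Columbia wild type (WT, stock CS60000), ivd1-2 and hml1-2, a pair of lines named for lesions in genes of leucine breakdown. The conditions were 0 h, 6, 24, 48 and 72 h of prolonged darkness, and 72 h more in the day and night cycle (72 h of light below). Per the labels, total RNA was made into stranded libraries and sequenced on an Illumina HiSeq2500. The labels call the 2 libraries of a group duplicates and state neither whether they came from separate plants nor at which time of day leaves were taken, so the p-values measure the spread between these samples.

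The deposited values are raw counts per gene, one set per library, with no normalization. The authors' processing notes name Trimmomatic 0.30, TopHat 1.4.1, SAMtools 0.1.19, Cuffdiff 2.1.1, HTSeq without a version and the TAIR10 build. The strand setting of the counting and the filters on alignments are not given in the sources used here, so counts of genes that overlap another gene, or that have near-identical copies such as LHCB1, LHCB2 and RBCS, are less certain. Locus codes were matched to the TAIR10.1 annotation for names and neighbouring genes only. Of the 28774 codes, 28009 had a match. Reads with several alignments had been removed or not marked before counting.

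Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the 18 groups, with a minimum count of 10 and a minimum total of 15. This left 19457 genes, and the genes removed held 0.0119% of all counts. Libraries were scaled by TMM. All 36 libraries entered a single fit with 1 coefficient for each of the 18 groups, which leaves 18 residual degrees of freedom, and each comparison was tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. A gene passed at an adjusted p under 0.05 with no minimum fold. "Rose" and "fell" below are used of genes that passed, and "not passing" of the rest. Levels are CPM on the TMM scale with the standard deviation over the 2 libraries, and log2 CPM used a prior count of 2. Folds against a group with 0 counts are lower bounds against a floor of 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval. These bounds and intervals cover counting error only. Depth ran from 13638597 to 49398596 counts per library.

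The comparisons were WT in each dark condition and in 72 h of light against WT at 0 h, WT at 72 h of darkness against 72 h of light, each mutant against WT in each condition and averaged over the 6 conditions, the mutants against each other at 72 h, and the difference between each mutant and WT in the change from 72 h of light to 72 h of darkness. The samples, tests, gene lists, named-gene rule and most variants of the analysis were fixed before the data were examined. The 29 lists hold 441 genes and were written from general knowledge. They cover branched-chain amino acid (BCAA) catabolism, other amino acid catabolism, BCAA synthesis, dark and starvation response, light harvesting and photosystems, the Calvin cycle, chlorophyll synthesis, chlorophyll breakdown, senescence, autophagy, peroxisomal beta-oxidation, starch metabolism, the circadian clock, flavonoids, aliphatic and indolic glucosinolates, salicylate defence, jasmonate response, abscisate response, mitochondrial dysfunction, heat shock proteins, cytosolic ribosome, DNA replication, cell wall loosening, and markers of flower, root, guard cell, phloem and epidermis. In the ribosome list 1 gene, RPS5B, was dropped before testing because the reference gives its code another symbol. Most genes of these lists are expressed in leaves. Lists were tested by camera with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 29 lists. Counts of members are given over all genes tested and adjusted over the list alone.

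The genes named are the 5 largest rises and falls among passing genes with a mean of at least 5 CPM in the higher group and replicates that do not overlap (in the averaged comparisons the same direction in all 6 conditions, in the differences no condition on replicates), the 2 to 4 members with the smallest p of each list past camera's threshold, and IVD and HML1. This rule covers WT at 72 h of darkness against light, each mutant at 72 h and averaged, and each difference. All other genes named were chosen after their values were seen.

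The variants fixed beforehand were DESeq2 size factors in place of TMM, no low-count filter, a mean of at least 5 CPM, DESeq2's own test, the replicate number as a block, only the groups compared in the fit, each library left out in turn, and camera with an estimated correlation. A fit to only the groups compared has few residual degrees of freedom. With a library left out, the lone library of its group is assumed to vary like the other groups, and TMM factors are estimated again, which shifts all genes of a comparison together by a small amount. Added after seeing the data were the salicylate list mean as a covariate, the ivd1-2 average without the later dark conditions, and camera without replicate 1 of ivd1-2 at 72 h of darkness. Genotype was also permuted within conditions, 100 splits per mutant. Counts were also simulated with the same depths and a fixed dispersion for all genes and groups, which was not taken from these data. On them edgeR recovered 51% of 4-fold and 2% of 2-fold changes in the comparison of 1 mutant at 72 h of darkness. It recovered 12% and 1% in a difference of responses, and 100% and 85% in the averaged comparison. Its false calls were 3 of 56, 0 of 13 and 9 of 194. DESeq2 recovered 59% and 6% in the first of these with 18 false calls of 83. Without any simulated change edgeR made 0 calls. Camera with the preset correlation recovered the 1 list shifted (adjusted p = 1.99e-13) and called 1 other list.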

Results

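Transcripts were counted in leaves of WT, ivd1-2 and hml1-2 plants at 0 h, after 6, 24, 48 and 72 h of darkness, and after 72 h more of day and night cycles. Each of the 18 groups had 2 libraries. Depth ran from 13638597 counts in WT at 0 h (replicate 2) to 49398596 in WT at 24 h of darkness (replicate 1). Plastid genes held 0.0515 to 0.215% of counts and mitochondrial genes 0.0166 to 0.0755%. RCA, the rubisco activase gene, had the most counts of any gene at 0 h and in 72 h of light, with 1.54 to 2.00% of counts, which are not adjusted for transcript length. The first principal component held 62.7% of the variance and placed WT at -151.3 at 0 h, -6.38, 56.8, 108.2 and 132.9 after 6, 24, 48 and 72 h of darkness, and -153.6 in 72 h of light. Replicate 1 of ivd1-2 at 72 h of darkness stood apart on the second component (10.96% of the variance) at 180.6, against 69.24 for the next highest library. Its Pearson correlation with replicate 2 across genes, which are not independent, was 0.884, against at least 0.931 in the other 17 groups. The salicylate list averaged 4.919 log2 CPM in this library and 0.4274 in replicate 2. Replicates also parted in these genes in hml1-2 at 0 h (5.655 and 0.36), WT at 0 h (4.911 and 0.4119) and hml1-2 in 72 h of light (4.515 and 0.5062). In ivd1-2 both were high at 0 h (3.992 and 3.656), 6 h of darkness (3.282 and 5.196) and 72 h of light (4.435 and 4.789).

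The lesions named by the mutant lines were read from the transcripts of the genes concerned. IVD (AT3G45300) encodes isovaleryl-CoA dehydrogenase of leucine breakdown, and HML1 (AT2G26800) encodes hydroxymethylglutaryl-CoA lyase, the last enzyme of that pathway. Averaged over the 6 conditions, IVD in ivd1-2 was at 17.8% of WT (log2 -2.49, SE 0.14, adjusted p = 2.48e-10), and it passed in each condition, with log2 -2.24 at 0 h, -2.77, -2.95, -2.44 and -2.44 in darkness and -2.10 in 72 h of light. The call at 0 h (adjusted p = 0.0245) and in 72 h of light (adjusted p = 0.0329) was lost without any 1 of 3 of the 4 libraries compared. IVD in ivd1-2 was at 4.69 ± 2.17 CPM (SD, n = 2) at 0 h and 376.6 ± 109 at 72 h of darkness, a change within the mutant that was not tested, and the difference in its change from light to darkness at 72 h was not past the threshold (log2 -0.34, adjusted p = 0.732). HML1 in hml1-2 was at 59.2% of WT on average (log2 -0.76, SE 0.0624, adjusted p = 3.98e-07). Tested by condition it passed only at 24 h of darkness (log2 -0.997, adjusted p = 0.0186), a call lost without any 1 of the 4 libraries, and its log2 was -0.72 at 0 h, -0.79 at 6 h, -0.65 at 72 h of darkness and -0.59 in 72 h of light.

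**Figure D1:**
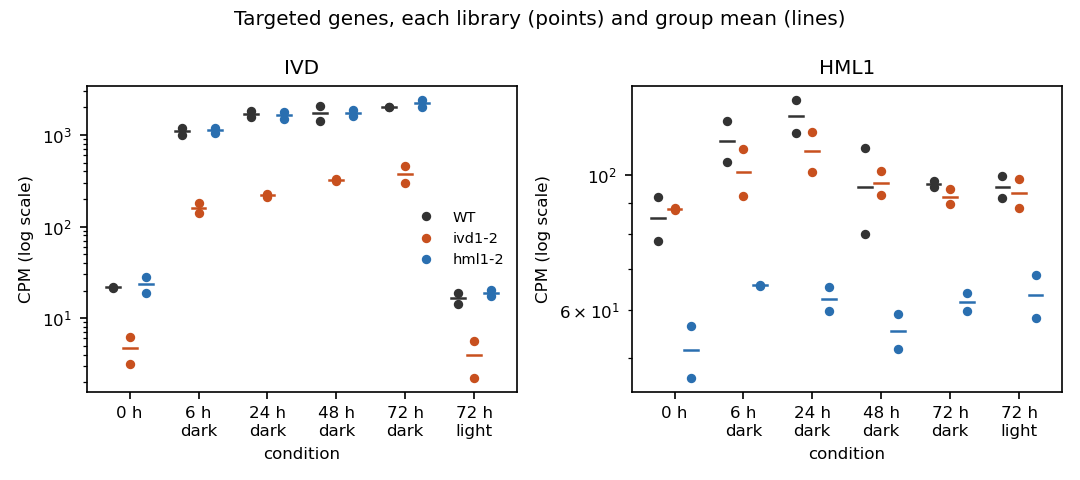
Level of IVD and HML1 (CPM, log scale) in each of the 36 libraries by condition and genotype, with a point per library and a line at the mean of each group. IVD lay lower in ivd1-2 than in WT in each condition, at 17.8% of WT on average, and HML1 in hml1-2 was at 59.2% of WT.

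The response of WT to darkness was read against 0 h, from which the 6 h samples also differ in time of day by the labelled hours. Genes of BCAA catabolism were among those that moved within 6 h: 16 of 19 measured rose and 0 fell, with a median log2 of 3.2 (camera adjusted p = 1.37e-16, and 0.00541 with an estimated correlation). At 24, 48 and 72 h the list rose by medians of 3.89, 3.9 and 4.38, with adjusted p = 0.0135, 0.0433 and 0.0419 with an estimated correlation. IVD went from 21.66 ± 0.205 CPM at 0 h to 1098 ± 152 at 6 h, 1696 ± 181 at 24 h, 1749 ± 484 at 48 h and 2037 ± 15.5 at 72 h (log2 5.66, 6.29, 6.34 and 6.56). HML1 rose at 6 h (log2 0.42, adjusted p = 0.0314) and 24 h (0.56, adjusted p = 0.0043). Other amino acid catabolism rose with medians of 2.43, 3.03, 3.11 and 3.18, and kept an adjusted p of at most 0.029 with an estimated correlation at all 4 times. Genes of dark and starvation response had risen by 6 h, 14 at 6 h and 15 at each later time, as had abscisate response, with 10 at 6 h and 14 at each later time.

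Photosynthesis genes fell in WT in darkness. Of 37 genes of light harvesting and photosystems, 6 fell and 2 rose at 6 h (median log2 -0.205), 35 fell at 24 h (-2.28), 36 at 48 h (-3.33) and 37 at 72 h (-3.93). Of 16 Calvin cycle genes, 14 fell at 6 h, 15 at 24 h and 16 at 48 and 72 h. Autophagy genes rose in steps of 16, 22, 22 and 22 of 31. Aliphatic glucosinolate genes fell at each time, 19, 16, 13 and 18 of 20, with medians of -4.07, -2.73, -2.01 and -6.27 (-5.22 at 72 h with genes near 0 counts at their bounds). At 6 h their count was 12 without replicate 2 of WT at 6 h. DNA replication genes fell in counts of 5, 13, 13 and 11 of 14, the first of which was 3 without replicate 1 of WT at 0 h, 1 without replicate 2 of it, 2 without replicate 1 of WT at 6 h and 1 without replicate 2. BCAA synthesis had 2 rising and 5 falling genes at 6 h and 7 falling genes at each later time.

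Over all genes, 4086 rose and 3735 fell at 6 h, 5050 and 4991 at 24 h, 5420 and 5749 at 48 h, and 5905 and 6273 at 72 h. The time of day of sampling is not given in the sources used here. By the labelled hours, 24, 48 and 72 h are whole days after 0 h, and 6 h is not. No light control was sampled at 6 h, so darkness and time of day cannot be told apart there. A smaller difference in time of day at the later hours is not excluded. Salicylate defence had 3, 10, 5 and 8 falling genes, counts that rested on single libraries. At 6 h the 3 became 0 without replicate 1 of WT at 0 h or either library at 6 h, and 7 without replicate 2 at 0 h. The 10 at 24 h became 0 without replicate 1 at 0 h or either library at 24 h. At 48 h the 5 became 1 without replicate 1 at 0 h or replicate 2 at 48 h, and 3 without replicate 1 at 48 h, and the 8 at 72 h became 1, 1 and 3 without replicate 1 at 0 h, replicate 2 at 72 h and replicate 1 at 72 h. Also at 6 h, the 11 rising senescence genes became 6 without replicate 2 at 0 h and 7 without replicate 1 at 6 h, the 5 falling indolic glucosinolate genes became 3 without replicate 1 at 0 h and 2 without replicate 2 at 6 h, and the 8 falling ribosome genes became 5 without replicate 2 at 6 h.

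**Figure D2:**
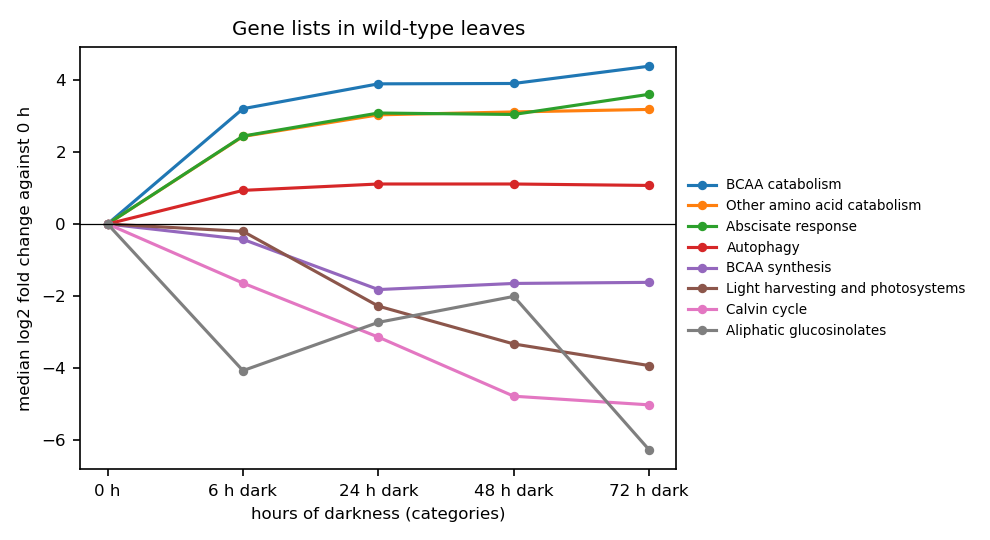
Median log2 fold change against 0 h of 8 gene lists in WT by hours of darkness, with a line per list. The BCAA catabolism list stood at 3.2 by 6 h and 4.38 by 72 h, while light harvesting went from -0.205 to -3.93.

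Darkness was set against light of the same age in WT at 72 h, and 6199 genes rose and 6170 fell, 63.6% of those tested. Genes that break down amino acids were the clearest group to rise. Of 19 BCAA catabolism genes, 14 rose, 1 fell and 4 did not pass (median log2 4.49, camera adjusted p = 8.32e-11, and 0.0405 with an estimated correlation). HDH1 (3-hydroxyisobutyrate dehydrogenase) was at 139.4 ± 21.6 CPM in darkness and 4.864 ± 0.0696 in light (log2 4.84, SE 0.255, adjusted p = 4.81e-12). DIN4, of the branched-chain ketoacid dehydrogenase, was at 870.6 ± 16.4 and 14.8 ± 2.76 (log2 5.88), ALDH6B2 at 834.7 ± 88 and 18.25 ± 2.9 (5.52), and IVD had log2 6.94. The list also held ETHE1, not an enzyme of BCAA breakdown itself, at 583.3 ± 15 and 27.79 ± 1.1 (4.39). Of 20 genes of other amino acid catabolism, 17 rose, 2 fell and 1 did not pass (median 3.18, camera adjusted p = 1.63e-09, and 0.0201 with an estimated correlation). Among them the tyrosine breakdown genes HGO (3265 ± 33.7 against 45.74 ± 19.2 CPM, log2 6.16) and HPD (1751 ± 146 against 77.89 ± 13, log2 4.49) and the methionine gamma-lyase gene MGL (log2 6.56) rose. BCAA synthesis went the other way, with 1 gene up (IPMS1, log2 1.25), 7 down and 3 not passing (median -1.83, camera adjusted p = 0.0706). The plastid aminotransferase gene BCAT3 (-2.63) and the threonine deaminase gene OMR1 (-2.77) were among those that fell. Counts adjusted over the list alone equalled those over all genes in each list of this comparison unless given.

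Starvation, senescence and recycling genes rose beside them. In the dark and starvation list 15 rose, 1 fell and 1 did not pass (median log2 2.67), with DRM2 at 2466 ± 445 against 7.827 ± 5.05 CPM and TPS11 (3.24), TPS10 (2.65) and KMD4 (2.67) also higher. In the abscisate list 13 rose, 0 fell and 2 did not pass (median 3.17), with RD29A at 580.6 ± 61.3 against 5.329 ± 0.98 CPM, RD29B at 139.7 ± 21.2 against 0.2723 ± 0.207, RAB18 at 1066 ± 21.6 against 12.25 ± 2.48 and HB12 (2.76) higher. The clock list had 10 up, 4 down and 0 not passing (median 5.34), with PRR5 (8.52), PRR3 (7.81), TOC1 (6.07) and ELF3 (4.07) higher. These 3 lists passed camera at adjusted p = 1.41e-07, 4.97e-06 and 1.13e-05, and each had adjusted p = 0.0603 with an estimated correlation. Both groups are labelled 72 h, but the time of day of sampling is not given, so a difference in it is not excluded for the clock genes. In senescence 15 rose, 1 fell and 5 did not pass (median 2.5, camera adjusted p = 0.000541, and adjusted p = 0.241 with an estimated correlation), among them WRKY22 (3.11), SAG20 (2.95) and EIN3 (2.49). In autophagy 24 rose, 2 fell and 5 did not pass (median 1.21, camera adjusted p = 1.71e-05, and adjusted p = 0.241 with an estimated correlation), among them ATG8B (5.01), ATG13A (2.32), ATG18G (1.90) and ATG4A (1.28). In peroxisomal beta-oxidation 11 rose (12 adjusted over the list alone), 1 fell and 5 did not pass (median 1.9, camera adjusted p = 0.000635, and adjusted p = 0.2 with an estimated correlation), with ACX4 (3.18), CSY2 (3.13) and AIM1 (1.91) higher and PMDH2 (-3.55) lower.

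Plastid and biosynthetic genes fell. Light harvesting and photosystems had 36 of 37 genes lower (median log2 -3.92), with LHCB3 at 120.3 ± 26.1 against 8382 ± 121 CPM and PSAK at 33.62 ± 1.74 against 2494 ± 279. DNA replication had 11 lower and 3 not passing (median -3.86, or -3.76 with bounds), among them MCM5 (-5.10) and MCM4 (-4.50). Camera gave these lists adjusted p = 1.47e-19 and 0.000969, and adjusted p = 0.108 with an estimated correlation for each. In the Calvin cycle 16 of 16 fell (median -4.84), with RCA at 381.5 ± 25.1 against 18590 ± 177 CPM, and in flavonoids 9 of 12 fell and 3 did not pass (median -4.45), with CHS at -7.02, UGT78D2 at -4.59 and PAL2 at -4.40. Their camera adjusted p was 8.6e-13 and 0.000863, and adjusted p = 0.0603 with an estimated correlation for both. Chlorophyll synthesis had 15 lower and 1 higher (median -4.22, camera adjusted p = 1.63e-09, and adjusted p = 0.162 with an estimated correlation), with CHLH at -6.00, CHLI1 at -4.62 and HEMA1 at -4.46. In starch metabolism 12 fell and 4 rose (median -2.09), with BAM3 at 50.94 ± 15.6 against 1360 ± 95.2 CPM, APS1 at -6.22 and GBSS1 at -5.63. In aliphatic glucosinolates 19 of 20 fell (median -6.16, or -5.2 with bounds), with IPMI2 at -6.87, MYB28 at -4.93 and UGT74C1 at -4.53. Camera gave the last pair 0.000491 and 3.37e-05, and adjusted p = 0.241 with an estimated correlation for each.

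The remaining lists did not pass camera in WT. Chlorophyll breakdown had 5 up, 2 down and 1 not passing (median log2 1.69), with NYE2, NYC1, PPH and PAO among the rising genes. Indolic glucosinolates had 5 down (6 adjusted over the list alone) and 3 not passing, and the ribosome list 1 up, 8 down and 5 not passing. Jasmonate response was split, 3 up, 3 down and 7 not passing. Salicylate defence had 0 up, 3 down (ICS1, PAD4 and CYP71A13; 0 adjusted over the list alone) and 17 not passing, with a median of 0.253 and a mean of 0.00875 against a camera direction of down. The 3 became 0 without either library at 72 h of darkness and 1 without replicate 1 in light. Mitochondrial dysfunction had 5 up and 5 not passing (median 0.563), which became 1 without replicate 1 in darkness or replicate 2 in light and 2 without replicate 1 in light. Heat shock proteins had 2 up (1 adjusted over the list alone) and 6 not passing, and cell wall loosening 3 up, 5 down and 4 not passing, with EXPA1, EXPA5 and EXPA8 lower and XTH22 and XTH24 higher. Of the markers, flower had 2 up (PI and SOC1) and 3 not passing, root 1 up (CASP2) and 1 not passing, guard cell 2 up, 2 down and 2 not passing (1 and 1 without replicate 1 in darkness), phloem 1 down (PP2-A1) and 2 not passing (3 down without replicate 2 in darkness), and epidermis 3 down (CUT1, FDH and PDF1) and 3 not passing.

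The largest changes in WT at 72 h were in genes with 0 counts in the lower group, so their folds are bounds. CSLG2 was at least 311-fold higher in darkness, AT1G71250 at least 267-fold, FLP1 at least 244-fold, and ACS2 and AT5G48110 at least 176-fold. In darkness they were at 13.04 ± 16.8, 11.02 ± 4.54, 9.887 ± 7.51, 7.296 ± 5.43 and 7.166 ± 2.03 CPM in that order. The replicates of CSLG2, FLP1 and ACS2 parted widely, and the bounds hold for the group and not for each library. EXPB1 was at least 200-fold lower, FLA15 at least 157-fold, GHR1 at least 151-fold, AT5G02890 at least 120-fold and GIS at least 92-fold.

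The passing of 72 h without a change in the light and dark cycle was tested in WT against 0 h. IVD was at 16.61 ± 3.07 CPM against 21.66 ± 0.205. No gene passed by edgeR, 666 had an unadjusted p under 0.05, and DESeq2 called 15, of which 7 were higher and 8 lower. No list had a passing member over all genes, and 1 mitochondrial dysfunction gene fell adjusted over the list alone. Camera with the preset correlation called 9 lists, led by senescence (6.41e-07) and salicylate defence (9.13e-07, median log2 -2.91), and each had adjusted p of at least 0.44 with an estimated correlation. The salicylate list mean was 4.911 and 0.4119 log2 CPM in the replicates at 0 h and 1.254 and 0.5163 in 72 h of light.

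In ivd1-2 before and early in darkness, few genes were called against WT. At 0 h AT5G11330, an oxidoreductase gene, was higher (log2 1.45, adjusted p = 0.000448) and IVD lower. At 6 h IVD, MLO3 (AT3G45290; -5.28, adjusted p = 0.000138) and ILA (AT1G64790; -1.87, adjusted p = 4.34e-05) were lower. In 72 h of light AT5G11330 was higher (1.06, adjusted p = 0.0226) and ILA (-1.29, adjusted p = 0.0139) and IVD lower. These were all calls in the 3 conditions, with 66, 1757 and 831 genes at an unadjusted p under 0.05, and AT5G11330, MLO3 and ILA were named at 0 and 6 h after their values were seen. The 66 at 0 h and 831 in light are fewer than an even spread of p-values over the 19457 genes would give. Few calls there do not show that few genes differed. At 0 h AT5G11330 was lost without replicate 1 of WT, in light it was lost without any 1 of 3 libraries and ILA without either ivd1-2 library, and at 6 h 13 genes were called without replicate 1 of ivd1-2.

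At 6 h and 0 h in ivd1-2, and in 72 h of light, IVD was the 1 list gene that passed over all genes. At 6 h the salicylate list stood 4.09 higher at the median (4 with bounds), and 13 members rose adjusted over the list alone (camera adjusted p = 2.96e-15, and adjusted p = 0.242 with an estimated correlation). Adjusted over the list alone 3 indolic glucosinolate and 1 jasmonate genes rose, and 3 starch, 2 epidermis and 1 abscisate genes fell. Camera called 12 lists at 6 h and 4 at 0 h, with adjusted p of at least 0.212 with an estimated correlation in each. In 72 h of light it called 14 lists. Salicylate defence was again higher (median 3.63, camera adjusted p = 1.44e-16, and adjusted p = 0.19 with an estimated correlation), and so were heat shock proteins (3.33, 6 genes adjusted over the list alone, camera adjusted p = 4.61e-08, and adjusted p = 0.181 with an estimated correlation). The other 12 had adjusted p of at least 0.181 with an estimated correlation.

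More genes were called between ivd1-2 and WT at 24 and 48 h of darkness. At 24 h BCAT3 rose (log2 1.27, SE 0.216, adjusted p = 0.00701, 14.66 ± 2.91 against 6.083 ± 0.977 CPM), and RD29A (-2.03, adjusted p = 0.00949) and RD29B (-2.11, adjusted p = 0.0401) fell. At 48 h BCAT3 (1.98, SE 0.222, adjusted p = 2.25e-05, 23.72 ± 0.274 against 6.024 ± 1.35 CPM) and OMR1 (1.32, adjusted p = 0.0214) rose and RD29B fell (-2.31, adjusted p = 0.00533, 8.211 ± 1.41 against 40.66 ± 8.58 CPM). The starch beta-amylase gene BAM3 (-1.71), the regulator of daylength response CDF1 (-1.75), MYB28 (-2.55), GSA1 (-0.62) and ATG1C (-0.61) fell at 48 h, and ATG4A (0.58) and C4H (0.98) rose. In all, 49 genes rose and 46 fell at 24 h, and 380 rose and 341 fell at 48 h. Both totals were larger with the replicate number as a block, as given below. MLO3 fell in both (-8.16 and -7.97).

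Of the lists, BCAA synthesis passed camera at 24 h (median 0.369, 1 gene up and 2 adjusted over the list alone, camera adjusted p = 0.000101, and adjusted p = 0.943 with an estimated correlation) and at 48 h (median 0.69, 2 up and 5 adjusted over the list alone, camera adjusted p = 9.2e-07, and adjusted p = 0.475 with an estimated correlation). Abscisate response at 24 h had 2 genes down over all genes and over the list alone, with a median of -0.358 (camera adjusted p = 0.000944, and adjusted p = 0.943 with an estimated correlation). BCAA catabolism at 24 h had IVD down and a median of -0.191 (camera adjusted p = 0.0101, and adjusted p = 0.943 with an estimated correlation). At 48 h aliphatic glucosinolates had 4 down, 13 adjusted over the list alone (median -3.13, or -2.82 with bounds, camera adjusted p = 8.87e-09, and adjusted p = 0.437 with an estimated correlation). Indolic glucosinolates had 2 down, 5 adjusted over the list alone (median -1.52, camera adjusted p = 1.51e-05, and adjusted p = 0.437 with an estimated correlation). Of the 95 calls at 24 h, the count was 18, 23, 18 and 15 without replicate 1 or 2 of ivd1-2 or replicate 1 or 2 of WT, BCAT3 was lost without either replicate 1, RD29A without replicate 2 of ivd1-2 or replicate 1 of WT and RD29B without any 1 of the 4. The 721 at 48 h became 269 without replicate 1 of ivd1-2, 370 without replicate 2 and 179 without replicate 1 of WT, RD29B was lost without replicate 1 of ivd1-2, C4H without any 1 of the 4 libraries, OMR1, CDF1, GSA1 and ATG4A without any 1 of 3 and MYB28 and ATG1C without either of 2, and the 4 aliphatic glucosinolate genes became 1, 0 and 0 without replicate 1 or 2 of ivd1-2 or replicate 1 of WT.

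At 72 h of darkness 2460 genes rose and 2075 fell in ivd1-2 against WT, and a fit to these 4 libraries alone, with few residual degrees of freedom, called 0. Of 15 abscisate genes 5 fell, among them RD29B, RD29A, RAB18 and COR15A. RD29B was at 10.99 and 25.58 CPM against 139.7 ± 21.2 in WT (log2 -2.93, SE 0.456, adjusted p = 0.000243), RD29A at 145.3 ± 25.6 against 580.6 ± 61.3 (-1.999, SE 0.364, adjusted p = 0.000922), RAB18 at 228.1 ± 112 against 1066 ± 21.6 (-2.22, adjusted p = 0.00281) and COR15A at 4.241 ± 0.8 against 38.14 ± 5.47 (-3.17, adjusted p = 0.00553). RAB18 and COR15A were lost without replicate 1 of ivd1-2 (log2 values over the libraries left out of -2.62 to -1.8 and -3.21 to -2.96). In the list 0 rose, 5 fell (6 adjusted over the list alone) and 10 did not pass (median -0.731, camera adjusted p = 0.00382, and adjusted p = 0.891 with an estimated correlation). BCAT3 was at 27.47 ± 3.14 against 9.309 ± 0.274 CPM (1.56, SE 0.216, adjusted p = 7.59e-05) and OMR1 at 12.47 ± 2.76 against 5.191 ± 1.1 (1.26, SE 0.306, adjusted p = 0.00631), the 2 of 11 BCAA synthesis genes that rose. In hml1-2 at 72 h of darkness these 6 genes did not pass against WT, but neither did HML1, so this does not show that they were unchanged. Set directly against hml1-2, ivd1-2 had log2 -2.69 for RD29B, -2.03 for RD29A, -1.96 for RAB18, -2.93 for COR15A, 1.77 for BCAT3 and 1.16 for OMR1. All 6 passed. RAB18, COR15A and OMR1 were lost without replicate 2 of hml1-2, and RAB18 and COR15A also without replicate 1 of ivd1-2.

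Other groups rose at 72 h of darkness chiefly in replicate 1 of ivd1-2. Salicylate defence had 7 genes up (8 adjusted over the list alone) and 13 not passing (median 4.03, camera adjusted p = 0.0142, and adjusted p = 0.891 with an estimated correlation). ICS1 was at 1028 CPM in replicate 1 and 2.83 in replicate 2 against 0.9947 ± 0.518 in WT, and EDS5 (169.4 and 1.085), PBS3 (748.7 and 0.9691) and PAD4 (234.9 and 1.706) parted in the same way. Autophagy had 10 up (14 adjusted over the list alone), 1 down and 20 not passing (median 0.343, camera adjusted p = 0.00382, and adjusted p = 0.891 with an estimated correlation). ATG8H was at 545.7 and 35.97 CPM against 19.79 ± 0.887 and ATG12B at 2.422 ± 0.246 against 1.204 ± 0.186, while ATG1C fell (log2 -0.66, adjusted p = 0.00274). Peroxisomal beta-oxidation had 4 up (5 adjusted over the list alone) and 13 not passing (median 0.547, camera adjusted p = 0.0142, and adjusted p = 0.891 with an estimated correlation), with ACX1 at 639.4 and 256.4 against 174.7 ± 1.75 CPM and MFP2 at 404.2 and 200.2 against 116.5 ± 0.387. Epidermis markers had 3 down, also adjusted over the list alone, and 3 not passing (median -1.38, camera adjusted p = 0.0326, and adjusted p = 0.891 with an estimated correlation), with CUT1 at -1.25, FDH at -1.16 and GL2 at -1.76. Without replicate 1 of ivd1-2 the counts of rising genes were 0 in salicylate defence, 1 in autophagy and 0 in beta-oxidation, and the salicylate median was -0.098.

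The lists that did not pass camera at 72 h of darkness had few passing members. BCAA catabolism had 2 up (BCAT1 and BCE1B1), IVD down and 16 not passing, and other amino acid catabolism 3 up (POP2, GDH2 and PRODH2) and 17 not passing. Mitochondrial dysfunction had 4 up and 6 not passing, with AOX1A at 106.5 and 12.44 CPM against 4.627 ± 1.16 and AOX1D at 735.3 and 7.443. Dark and starvation response had 3 up and 14 not passing, senescence 3 up (4 adjusted over the list alone), 2 down and 16 not passing, jasmonate 3 up and 10 not passing, indolic glucosinolates 3 up, 2 down and 3 not passing, flavonoids 2 up, 1 down and 9 not passing, and DNA replication 3 up, 2 down and 9 not passing. Starch metabolism had 2 down (1 adjusted over the list alone), with BAM3 at 18.13 ± 5.3 against 50.94 ± 15.6 CPM, and the clock list 1 down, CDF1 at 9.005 ± 4.53 against 40.62 ± 5.24. Light harvesting had 1 up (LHCB4.3; 0 adjusted over the list alone), heat shock proteins 1 up (HSP101), chlorophyll synthesis 1 down (GSA1), aliphatic glucosinolates 1 down (MYB28) and guard cell markers 2 down. The Calvin cycle, chlorophyll breakdown, ribosome, cell wall, flower, root and phloem lists had 0 passing genes.

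The largest rises at 72 h of darkness were AT5G60930, at least 113-fold, AT2G24285, at least 108-fold, AT5G22530, at least 99.2-fold, FMO1 with a ratio of 1310 (448 to 6350) and AT4G11655 with 1020 (183 to 40400). These 5 were at 12.71, 12.07, 11.06, 147.4 and 38.4 CPM in replicate 1 of ivd1-2 and 0.03876, 0.1163, 0.1551, 0.3101 and 0.07753 in replicate 2, and each call was lost without replicate 1. AT5G22530, FMO1 and AT4G11655 were also lost without either WT library. The largest falls were MLO3 (log2 -7.42, adjusted p = 4.78e-07, 3.021 ± 2.03 against 514.7 ± 97.3 CPM), LUP1 (-4.63, adjusted p = 0.00264), XDH2 (-4.22, adjusted p = 0.000239), PYD4 (-3.93, adjusted p = 0.0086) and CYP708A3 (-3.89, adjusted p = 6.13e-05), of which LUP1 and PYD4 were lost without replicate 1 of ivd1-2 (-4.453 and -4.069).

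Replicate 1 of ivd1-2 carried much of the 72 h result. The 4535 calls were 1098 without it, 7689 without replicate 2, 2400 without replicate 1 of WT and 2177 without replicate 2 of WT. Of the 4535, 913 were called without replicate 1 and all 913 had the same direction. Among list genes, 8 of the 75 called passed whichever of the 4 libraries was left out: IVD, BCAT3 (log2 1.64 to 1.67), RD29A (-2.05 to -1.79), RD29B (-3.45 to -2.45), BAM3 (-1.83 to -0.995), CDF1 (-2.59 to -1.74), ATG1C (-0.653 to -0.479) and ATG12B (0.894 to 1.33), as did MLO3 (-8.12 to -6.85) and ILA (-3.86 to -3.37). OMR1 was lost without replicate 1 of WT. Without replicate 1 of ivd1-2 the rising genes of BCAA catabolism, DNA replication, other amino acid catabolism, dark response, senescence, flavonoids, indolic glucosinolates, jasmonate and mitochondrial dysfunction were 0 and the falling abscisate genes 2, RD29A and RD29B. Without replicate 2 of ivd1-2 the list counts were larger: 18 autophagy, 13 salicylate, 9 beta-oxidation, 6 other amino acid, 5 dark response, 4 BCAA catabolism and 3 heat shock genes rose, and 10 light harvesting, 6 Calvin cycle, 5 chlorophyll synthesis, 5 starch, 4 ribosome, 4 cell wall and 2 BCAA synthesis genes fell, with 1 falling epidermis gene. Without replicate 1 of WT salicylate, jasmonate, mitochondrial, dark response and senescence each had 1 rising gene, epidermis had 0 falling and DNA replication 1 up and 2 down. Without replicate 2 of WT 5 autophagy, 1 salicylate, 1 mitochondrial, 1 dark response, 1 indolic, 0 jasmonate, 0 senescence and 0 DNA replication genes rose. With DESeq2 size factors the share of calls that were higher went from 54.2 to 61.9%.

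**Figure D3:**
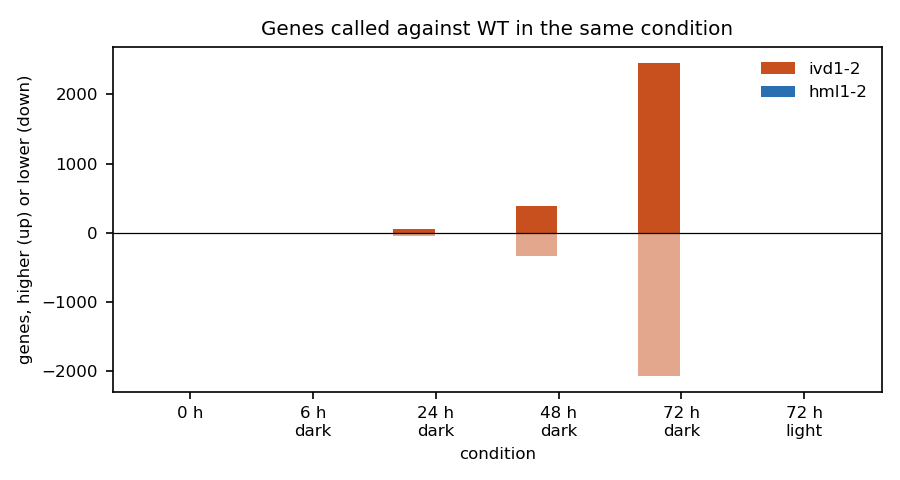
Number of genes higher (bars up) and lower (paler bars down) than WT at an adjusted p under 0.05 in ivd1-2 and hml1-2 in each condition. In ivd1-2 the calls went from 95 at 24 h to 4535 at 72 h of darkness, and hml1-2 had 1 or 2 in each condition.

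**Figure D4:**
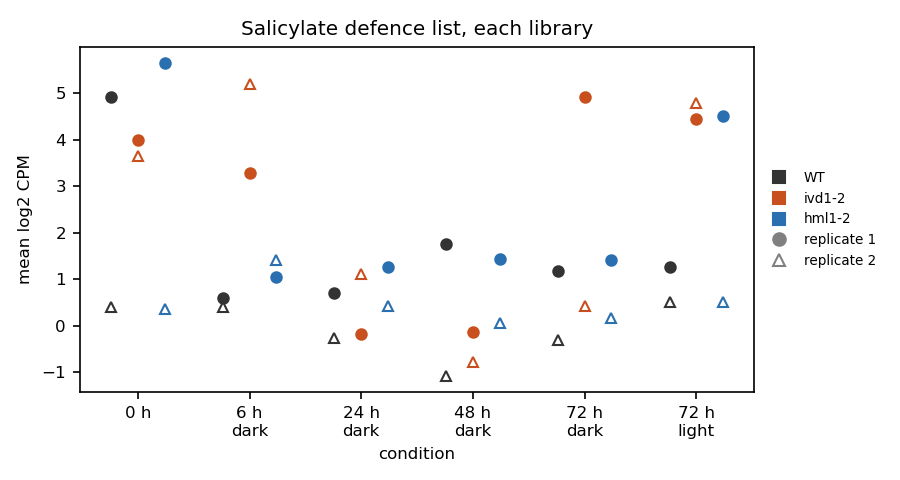
Mean log2 CPM of the salicylate defence list in each library by condition and genotype, replicate 1 as circles and replicate 2 as triangles. In ivd1-2 at 72 h of darkness the replicates lay at 4.919 and 0.4274, and in WT at 0 h at 4.911 and 0.4119.

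Averaged over the 6 conditions, ivd1-2 had 1531 genes higher and 1670 lower than WT. BCAT3 (log2 0.66, SE 0.0865, adjusted p = 4.71e-05) and OMR1 (0.63, SE 0.124, adjusted p = 0.00197) rose, and COR15A (-1.59, SE 0.289, adjusted p = 0.00105), RD29B (-1.42, SE 0.226, adjusted p = 0.000305), RD29A (-1.06, SE 0.15, adjusted p = 0.000101) and NCED3 (-0.59, adjusted p = 0.0158) fell. By condition BCAT3 passed only at 24, 48 and 72 h of darkness and OMR1 only at 48 and 72 h. In 72 h of light both were fitted lower in ivd1-2 than in WT without passing. Their differences of responses (1.99 and 1.49) therefore exceed their rises at 72 h of darkness (1.56 and 1.26). AOX1A rose by 1.37 (SE 0.285, adjusted p = 0.0031). MLO3 fell by an averaged -4.81 (adjusted p = 3.49e-11). Among genes with the same direction in all 6 conditions the largest falls were IVD, ILA (-2.201), AT5G52070 (-1.81, adjusted p = 1.85e-08), XDH2 (-1.77, adjusted p = 6.23e-05) and AT5G35480 (-1.51, adjusted p = 0.0126). Among the largest rises were AT2G45220 (3.42, adjusted p = 0.0406) and AT3G22600 (3.27, adjusted p = 0.0484), calls lost without any 1 of 15 and of 19 of the 24 libraries. They were 1.655 and 2.335 without replicate 1 of ivd1-2 at 72 h of darkness, and with the salicylate list mean as a covariate AT2G45220 turned to -0.1338. The other large rises, AT3G46080, AT4G08555 and GRX480, had groups of at most 3 counts, so no fold is given, and their calls too were lost without that library. The 3201 calls were 5882 without replicate 2 of ivd1-2 at 72 h of darkness, 384 without the 72 h dark condition and 14 without 48 and 72 h. With the replicate number as a block the count was larger, as given below.

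Camera called 14 lists in the averaged comparison, each with adjusted p = 0.701 with an estimated correlation. Genes rose in salicylate defence (5, or 9 adjusted over the list alone; median log2 1.6), heat shock proteins (5, or 6; median 1.41), autophagy (6 up and 1 down), beta-oxidation (4, or 7), mitochondrial dysfunction (3, or 4), other amino acid catabolism (3, or 4), BCAA synthesis (2, or 3) and senescence (3 up and 1 down, or 4 and 1). Examples were CBP60G (1.47), ICS1 (2.22) and EDS5 (2.2) of salicylate defence, ATG12B (0.42) and ATG8H (0.95) of autophagy, ACX1 (0.52) and LACS6 (0.55) of beta-oxidation, POP2 (0.40) and GDH2 (0.59) of amino acid catabolism, and SAG20 (0.57) and SAG14 (1.61) of senescence. Genes fell in abscisate response (4, or 6), light harvesting (4, or 0; LHCB3 -0.47 and PSAG -0.45), aliphatic glucosinolates (3, or 4; MYB28 -1.10), the Calvin cycle (2, or 1; TKL1 -0.23), chlorophyll synthesis (1, GSA1 -0.27) and epidermis markers (2, FDH -0.52 and CUT1 -0.43). Of 66 list genes called, 33 passed whichever library was left out, among them BCAT3, OMR1, RD29A, RD29B, COR15A, AOX1A, MYB28, ATG12B, ACX1 and POP2. ICS1 and EDS5 were lost without replicate 2 of ivd1-2 at 48 h or replicate 1 at 72 h of darkness, and NCED3 without replicate 1 of WT at 24 h, 72 h of darkness or 72 h of light.

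Leaving whole conditions out of the ivd1-2 average cost more. Among values of genes named by the rule, 20 kept direction and side of the threshold without 72 h of darkness and 46 lost the threshold. Without 48 and 72 h of darkness these were 15 and 51. Several list counts of the averaged comparison moved with 1 library. Heat shock proteins had 0 to 2 called genes without any 1 of 15 libraries, light harvesting 0 to 19 without any 1 of 13, aliphatic glucosinolates 1 to 5 without any 1 of 12 and senescence 2 to 9 without any 1 of 11. Salicylate defence had 1 without replicate 1 of ivd1-2 at 72 h of darkness, 3 without replicate 2 of ivd1-2 at 6 or 48 h or of WT at 6 h, 8 without replicate 1 of WT at 48 h, 9 without replicate 1 of WT at 0 h and 10 without replicate 2 of ivd1-2 at 72 h of darkness. The last library left out also gave 15 rising autophagy, 9 beta-oxidation, 5 BCAA catabolism, 5 dark response, 5 jasmonate and 3 indolic glucosinolate genes and 6 falling Calvin cycle, 5 starch, 5 chlorophyll synthesis, 3 flavonoid and 3 cell wall genes. Beta-oxidation had 7 without replicate 1 of WT at 0 h or of ivd1-2 at 6 h, and mitochondrial dysfunction had 5 without the first of these and 1 without replicate 1 of ivd1-2 at 72 h of darkness. Other amino acid catabolism had 1 without replicate 1 of WT at 24 h and 5 without replicate 1 of ivd1-2 at 6 h. Without replicate 2 of WT at 48 h 3 BCAA catabolism genes rose and 4 Calvin cycle genes fell, and without replicate 1 of WT at 6 h 4 starch genes fell.

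Whether ivd1-2 responded to darkness otherwise than WT was tested as the difference in the change from light to darkness at 72 h. Here 509 genes rose and 371 fell, and 0 lists passed camera, against 9 without replicate 1 of ivd1-2 at 72 h of darkness. A fit to the 8 libraries alone called 0 genes, and the fit with the replicate number as a block, given below, called more than the main fit. Among list genes BCAT3 (log2 1.99, adjusted p = 0.000794), OMR1 (1.49, adjusted p = 0.0471), BCAT1 (3.22, adjusted p = 0.0438), POP2 (1.31, adjusted p = 0.0415), DIN9 (3.62, adjusted p = 0.0204), ATG8H, ATG12B, C4H, UGT78D2 and ICS1 rose, and RD29B (-3.66, adjusted p = 0.0116) and CUT1 (-1.33, adjusted p = 0.0351) fell. They were named after their values were seen. With a library left out the lowest log2 was 0.687 for BCAT1, 1.62 for DIN9, 0.0716 for ATG8H (3.06 with all) and -0.628 for ICS1 (6.85 with all). For BCAT3, OMR1 and ATG12B it was 1.98, 1.41 and 1.04. Adjusted over the list alone 2 abscisate and 3 epidermis genes fell, and 2 indolic glucosinolate genes rose and 1 fell. The largest falls by the rule were MLO3 (-7.62, adjusted p = 1.95e-05), AT3G61198 (-5.38), LUP1 (-4.82), XDH2 (-3.83) and CYP708A3 (-3.78), of which AT3G61198 was lost without any 1 of 4 of the 8 libraries, LUP1 of 5 and XDH2 of 3. Among the largest rises, replicate 1 of ivd1-2 at 72 h of darkness stood above replicate 2 in each case: the asparaginase gene ASPGB1 (131.2 and 3.721 CPM), D27 (18.1 and 0.1551), RIPK (233.3 and 0.2713), LOX1 (1395 and 8.489) and AT1G04490 (44.23 and 0). Each of these calls was lost without replicate 1, where ASPGB1 was at 4.41, D27 at 1.467 and LOX1 at 0.6102, and RIPK turned to -1.735. In 72 h of light D27 was at 9.703 ± 2.9 CPM in ivd1-2 and 14.02 ± 0.728 in WT, against 0.08249 ± 0.117 in WT in darkness, and RIPK at 23.25 ± 6.37, 15.68 ± 0.58 and 0.6324 ± 0.506. The 880 calls were 459 without this library and 3763 without replicate 2 (4 salicylate, 12 autophagy, 4 beta-oxidation, 4 other amino acid, 3 BCAA catabolism, 3 dark response, 3 indolic and 3 jasmonate genes rising), 262 and 586 without replicate 1 or 2 of WT in darkness (3 epidermis genes falling without the latter), 231 and 356 without replicate 1 or 2 of ivd1-2 in light, and 287 and 357 without replicate 1 or 2 of WT in light. Of the 12 list genes BCAT3 alone passed in each of these fits, as did MLO3 and ILA. DESeq2 size factors shifted the median of all genes by 0.116 in this difference and by under 0.1 elsewhere, and took the share of calls that were higher from 57.8 to 69.2%.

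In hml1-2 few genes were called against WT in any condition. ILA was lower at 6 h of darkness (log2 -1.85), 24 h (-2.57), 48 h (-2.77), 72 h (-3.03, adjusted p = 1.3e-08, 88.85 ± 1.8 against 725.9 ± 8.56 CPM) and in 72 h of light (-1.20, adjusted p = 0.0194). AT5G11330 was higher at 0 h (1.29, adjusted p = 0.00288) and in 72 h of light (1.11, adjusted p = 0.0194), and HML1 lower at 24 h. These were all 8 calls by condition, with 82 to 450 genes at an unadjusted p under 0.05. An even spread of p-values over the 19457 genes would give more than that in each condition. The test was therefore conservative here, and few calls do not show that few genes differed. The call of AT5G11330 at 0 h was lost without replicate 1 of WT. In 72 h of light it was lost without replicate 1 of hml1-2 or of WT, and ILA without either hml1-2 library or replicate 1 of WT. Averaged over the conditions 3 genes rose, AT5G56370 (1.39, adjusted p = 0.00749), AT1G76820 (1.13, adjusted p = 0.0301) and AT5G11330 (0.86, adjusted p = 2.13e-07), and ILA and HML1 fell, and AT1G76820 was lost without any 1 of 11 of the 24 libraries. The change from light to darkness at 72 h was called different from that of WT for ILA alone (-1.83, adjusted p = 0.0119). AT5G56370, and ILA and AT5G11330 before 72 h, were named after their values were seen.

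Gene lists in hml1-2 had no passing member except HML1. At 48 h of darkness aliphatic glucosinolates stood lower, with 7 genes down adjusted over the list alone and a median log2 of -1.78 (-1.41 with bounds; camera adjusted p = 3.68e-22, and 0.0455 with an estimated correlation). In the same condition abscisate response stood higher (median 0.613, camera adjusted p = 9.3e-07, and adjusted p = 0.0683 with an estimated correlation) and DNA replication lower (-0.498, 2 genes adjusted over the list alone, camera adjusted p = 2.37e-05, and adjusted p = 0.0683 with an estimated correlation). At 72 h of darkness camera called autophagy, abscisate response, heat shock proteins and guard cell markers at 0.0433 each, with adjusted p = 0.919 with an estimated correlation. In 72 h of light it called 7 lists, with salicylate defence higher (median 2.59, camera adjusted p = 4.41e-10, and adjusted p = 0.589 with an estimated correlation), where the list mean was 4.515 log2 CPM in replicate 1 of hml1-2, 0.5062 in replicate 2, and 1.254 and 0.5163 in WT. The average had 11 lists and the difference of responses 7, with adjusted p of at least 0.795 and 0.427 with an estimated correlation.

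Both mutants shared the fall in ILA and the rise in AT5G11330 against WT. They were the 2 genes called in both averaged comparisons. Independent lists would give 0.236 shared higher and 0.172 shared lower calls, but both comparisons use the same WT libraries, so the lists are not independent. On average ILA changed by log2 -2.201 in ivd1-2 (SE 0.0779, adjusted p = 6.7e-14) and -2.04 in hml1-2 (SE 0.0774, adjusted p = 2.82e-13). The 12 WT libraries lay at 191.2 to 731.9 CPM and the 24 mutant libraries at 43.09 to 126.6. WT rose in darkness, from 208.2 at 0 h to 725.9 at 72 h, and stood at 259.8 in 72 h of light. At 72 h of darkness ILA was also lower in ivd1-2 than in hml1-2 (log2 -0.644, adjusted p = 0.0176), a call lost without replicate 1 of either. AT5G11330 was higher by 0.78 and 0.86 (adjusted p = 1.77e-07 and 2.13e-07), with WT at 16.33 to 50.42 and the mutants at 29.84 to 69.54 CPM, but at 72 h of darkness ivd1-2 had 0.10 (adjusted p = 0.701). MLO3, next to IVD in gene order, rose in WT from 4.084 CPM at 0 h to 131.3, 743, 598.2 and 514.7 in darkness. It was at 566.8 ± 14.9 CPM in hml1-2 at 72 h of darkness and at 2.39 to 4.93 in the ivd1-2 groups (averaged log2 -4.81, SE 0.24, adjusted p = 3.49e-11).

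Across 13049 genes, which are not independent, the averaged changes of the mutants correlated at 0.725. Because both comparisons use the same WT libraries, 20 simulations of unchanged mutants gave a mean of 0.499. With replicate 1 of WT set against ivd1-2 and replicate 2 against hml1-2 the correlation was 0.2, and -0.28 the other way round, with 2 shared calls in each. This split gives any difference between the WT replicates opposite signs in the 2 comparisons, which pushes the correlation down. It therefore does not decide how much the mutants share.

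**Figure D5:**
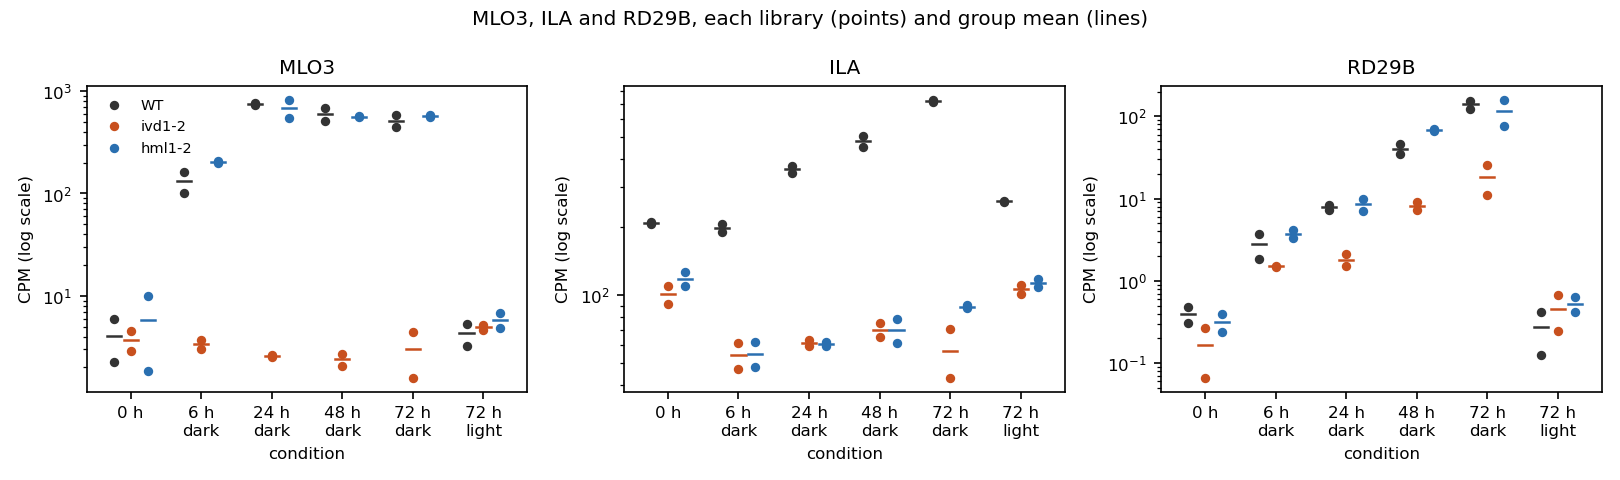
Level of MLO3, ILA and RD29B (CPM, log scale) in each library by condition and genotype, with a point per library and a line at the mean of each group. MLO3 was at 514.7 CPM in WT and 3.021 in ivd1-2 at 72 h of darkness, and ILA was lower in each mutant library (43.09 to 126.6 CPM) than in each WT library (191.2 to 731.9).

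The mutants were also compared with each other at 72 h. In darkness 2182 genes were higher and 1890 lower in ivd1-2 than in hml1-2, and 0 were called in a fit to the 4 libraries alone. The count was 952 without replicate 1 of ivd1-2, 7284 without replicate 2, 1740 without replicate 1 of hml1-2 and 1948 without replicate 2. Autophagy had 9 up (10 adjusted over the list alone) and 1 down, salicylate defence 6 up (7 adjusted over the list alone), beta-oxidation 5 up and abscisate response 4 down (5 adjusted over the list alone), each at camera adjusted p = 0.0356, and adjusted p = 0.957 with an estimated correlation. Mitochondrial dysfunction (4 up), heat shock proteins (1 up) and light harvesting had 0.0494, and adjusted p = 0.957 with an estimated correlation. Without replicate 1 of ivd1-2 these were 1 autophagy, 0 salicylate, 0 beta-oxidation and 0 mitochondrial genes up and 2 abscisate genes down. Without replicate 2 of ivd1-2 they were 18 autophagy, 12 salicylate and 10 beta-oxidation genes up. Without replicate 1 or 2 of hml1-2 they were 1 and 1 salicylate, 4 and 5 autophagy and 1 and 1 mitochondrial genes up, with 3 beta-oxidation genes up and 2 abscisate genes down without replicate 2. In 72 h of light IVD alone passed (log2 -2.28, adjusted p = 0.0336), a call lost without any 1 of 3 of the 4 libraries, with 105 genes at an unadjusted p under 0.05. Salicylate defence was higher there (median 0.844, camera adjusted p = 1.69e-08, and adjusted p = 0.372 with an estimated correlation).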

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

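The tests of WT libraries out of place, of a WT stock difference, of a batch that follows the replicate number and of sequencing depth within groups were chosen only after the result was seen.

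The dark response at 72 h was called different between ivd1-2 and WT for 880 genes and between hml1-2 and WT for 1, by a test of the difference itself. In ivd1-2 the log2 difference was 8.551 for ASPGB1, 7.278 for D27, 6.961 for RIPK and 6.946 for LOX1, and AT1G04490 stood at 22.12 CPM in darkness where WT had at most 3 counts. Each of these 5 calls was lost without replicate 1 of ivd1-2 at 72 h of darkness, with 4.41, 1.467, -1.735 and 0.6102 for the first 4, and the 880 ran from 231 to 3763 with each library left out. The difference was -7.621 for MLO3, -5.381 for AT3G61198, -4.819 for LUP1, -3.83 for XDH2 and -3.78 for CYP708A3. In hml1-2 it was -1.83 for ILA, and 7 gene lists passed camera with the preset correlation and none with an estimated one. Reads outside annotated genes, which enter no comparison, were 1.264% of aligned reads in WT at 72 h of darkness and 0.6965% in light.

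ILA was lower and AT5G11330 higher in both mutants, which share the same WT libraries. A few WT libraries out of place are excluded for ILA, since all 12 WT libraries lay above all 24 mutant libraries. A difference of the WT stock from both mutant lines, in sequence or in genes carried along, may give equal shifts in both. The mutants differed in ILA by log2 -0.162 (SE 0.0747, adjusted p = 0.189), little beside falls of -2.201 and -2.04, but at 72 h of darkness by -0.644 (adjusted p = 0.0176), which was lost without replicate 1 of either. This explanation stays open because the design confounds stock with genotype, and no biological explanation was tested. The shift in ILA also grew in darkness (difference -2.38 in ivd1-2 and -1.83 in hml1-2).

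The many calls in ivd1-2 at 72 h of darkness rest in part on replicate 1. Without it 1098 genes were called, 913 of them among the 4535, so for the other calls 1 divergent library and a response of the genotype cannot be told apart. With the salicylate list mean as a covariate 4217 genes were called, 3474 of them among the 4535 (76.6%) and in the same direction. A linear effect of this list that is equal in all conditions therefore does not account for most of these calls. An effect that differs at 72 h of darkness was not tested and stays open. In the averaged ivd1-2 comparison the covariate left 2024 calls, 1419 of them among the 3201 (44.3%).

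In the averaged comparison 1 of 100 splits of genotype within conditions, the real one, gave as many calls. It gave 2975 in this count, from a separate fit to the libraries split, against 774 in the highest other. This argues against chance for the count, but the splits do not hold fixed the replicate numbers, which carry some sample structure. For hml1-2 14 of 100 splits called at least as many genes as the real one. The real split called 8 in the same kind of separate fit, against 5 in the main fit. These splits do not exclude chance for the count, and they too mix the replicate numbers. The highest other called 4400, which points to a structure of the samples that these splits do not hold fixed. The splits with the most calls (4400, 4197 and 3490) ranked 5, 1 and 2 of 100 in the salicylate list difference between their groups. Those ranked 6 and 9 called 0, and in ivd1-2 those ranked 1 and 2 called 22 and 0, so the ranks do not settle it. The splits do not bear on ILA and HML1 singly (adjusted p = 2.82e-13 and 3.98e-07 in edgeR's averaged test).

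Salicylate defence genes differed between replicates of 1 group by up to 5.29 log2 CPM. A batch that follows the replicate number could give this: replicate 1 was the higher in 14 of 18 groups (exact sign test p = 0.0309, two-sided), but groups such as ivd1-2 at 6 h went the other way (3.282 and 5.196), so it cannot be told apart from plants that differed in defence. Sequencing depth stays open too: the deeper replicate had the higher list mean in 13 of 18 groups (exact sign test p = 0.0963, two-sided). Over the 18 groups the replicate differences in list mean and log2 depth had Pearson's r = 0.298 (permutation p = 0.227), Spearman's rho = 0.319 (permutation p = 0.196) and r = 0.315 without the 2 farthest groups. No biological explanation was tested, as the labels give none within a group.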

How the results depend on the processing

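The salicylate covariate, the averages without later dark conditions and camera without 1 library were chosen only after the result was seen. Where a count moved, the cause was not tested unless given.

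With DESeq2's own test the counts were 15 for WT in light against 0 h, 49, 337, 1327 and 18 for ivd1-2 at 6, 24 and 48 h and in light, 1788 for its difference, 3, 6, 12, 9, 2 and 9 for hml1-2 by condition, 16 for its average, 3 for its difference and 2 for ivd1-2 against hml1-2 in light. With the replicate number as a block they were 282 and 1391 for ivd1-2 at 24 and 48 h, 4930 for its average, 1758 for its difference, 4 and 8 for hml1-2 at 6 h and averaged, and 2 between the mutants in light. Replicate numbers carry some sample structure: 119 of 153 pairs of groups had correlated replicate differences (above 0.1 across genes, median 0.338), and all 36 libraries matched others of their own number best. The 2 libraries of a group mirror each other in this match, so the 36 are the outcomes of 18 groups. With the salicylate covariate they were 7, 246, 1288 and 1 for ivd1-2 at 6, 24 and 48 h and in light, 2024 averaged, 2221 for the difference, 2 for hml1-2 at 6 h and 0 between the mutants in light. The ivd1-2 average was 384 without 72 h of darkness and 14 without 48 and 72 h. Fits to only the groups compared, with few residual degrees of freedom, gave 0 for ivd1-2 at 72 h of darkness, its difference, both comparisons of the mutants, hml1-2 at 72 h in darkness and light and its difference, and 458 for ivd1-2 in light. IVD in ivd1-2 did not pass in that fit at 72 h of darkness (log2 -2.35) or in light (-2.12), nor with the covariate in light (-2.03). In hml1-2 at 24 h the count was 1 with DESeq2 size factors and 1 with no low-count filter, where the edgeR count was 2.

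With each library left out, counts ran from 5532 to 6312, 7896 to 8455, 9201 to 9833 and 10523 to 10773 in WT at 6, 24, 48 and 72 h, 0 to 0 in light against 0 h and 10454 to 10728 in darkness against light. In ivd1-2 they ran from 0 to 2 at 0 h, 3 to 13, 15 to 23, 179 to 588 and 1098 to 7689 in darkness, 0 to 2 in light, 2350 to 5882 averaged and 231 to 3763 for the difference. In hml1-2 they ran from 0 to 1, 1 to 2, 1 to 1, 1 to 2, 1 to 1 and 0 to 2 by condition, 4 to 6 averaged and 1 to 1 for the difference, and between the mutants from 952 to 7284 in darkness and 0 to 1 in light. IVD log2 ran from -2.55 to -2.17 at 72 h of darkness, -2.94 to -1.61 in light and -2.62 to -2.40 averaged, and HML1 from -0.72 to -0.58, -0.73 to -0.52 and -0.81 to -0.72. Factors re-estimated in each fit move all genes a little, so such a range need not hold the value from all libraries.

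Lists past camera's threshold fell with an estimated correlation from 15 to 2 in WT at 72 h and to 0 from 5, 14, 14, 4, 7, 11 and 7 in ivd1-2 at 72 h of darkness, in light and averaged, and in hml1-2 at 72 h of darkness, in light, averaged and for the difference. Without replicate 1 of ivd1-2 at 72 h of darkness they were 3 there, 8 averaged and 9 for the difference. Genes named by the rule turned in 5 cases. Without that library these were PAD4 (-0.2112) and PBS3 (-0.4256) at 72 h of darkness and AT1G04490 (fitted value -3.583) and RIPK (-1.735) in the difference. With the covariate it was AT2G45220 averaged (-0.1338). Genes named outside the rule could also turn with a library left out, such as ICS1 in the difference (lowest -0.628) and PRODH2 at 72 h of darkness (lowest -0.0352). Without replicate 1 of WT at 72 h of darkness PAD4, PBS3 and RIPK had their highest values, 7.465, 9.747 and 8.395. Over all alternatives 5896 values of named genes kept direction and side of the threshold, 543 lost the threshold and 68 gained it. On counts simulated with a fixed dispersion 2% of 2-fold changes within 1 condition were recovered. At that dispersion and these depths, 2 libraries per group would miss most changes of that size. This recovery was not computed at the spread of these data.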

Other observations

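The tests of a shared stock difference at MLO3 and of ivd1-2 running ahead of WT were chosen only after the result was seen.

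BCAT3 and OMR1 stood higher in darkness in ivd1-2 than in WT. In WT both fell from light to darkness at 72 h (log2 -2.63 and -2.77), and in ivd1-2 they went from 42.93 ± 3.63 to 27.47 ± 3.14 CPM and from 30.07 ± 3.43 to 12.47 ± 2.76. BCAT3 stood above WT at 24, 48 and 72 h (1.27, 1.98 and 1.56) and OMR1 at 48 and 72 h (1.32 and 1.26). RD29B, of the abscisate list, was at 1.806, 8.211 and 18.29 CPM in ivd1-2 after 24, 48 and 72 h against 7.822, 40.66 and 139.7 in WT. In the difference of responses it was the 1 abscisate gene of 15 that passed over all genes, and the list did not pass camera. XDH2 and CYP708A3, at 0.6405 and 0.3405 CPM in ivd1-2 at 72 h of darkness, were at 11.99 and 5.134 in WT. Neither BCAT3, OMR1 nor RD29B passed in hml1-2, whose lesion is in the same pathway and whose HML1 transcript was still at 59.2% of WT. By condition HML1 itself passed there only at 24 h of darkness, so genes that did not pass can still have changed. At 72 h of darkness ivd1-2 against hml1-2 gave log2 1.77 for BCAT3, 1.16 for OMR1 and -2.69 for RD29B. All passed, and OMR1 was lost without replicate 2 of hml1-2.

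Lower abscisate genes in ivd1-2 at 72 h of darkness might come from ivd1-2 running ahead of WT along the dark response, in which case they would be higher, since the list median was higher at 72 than at 24 h of darkness in hml1-2 (by log2 0.631, from library means and not tested). The median log2 of the 15 genes was -0.731 against WT, and from the mean log2 CPM of the libraries -0.794 (-1.11 with replicate 2 alone), and 12 of the 14 genes higher at 72 h than at 24 h in hml1-2 were lower in ivd1-2. This argues against running ahead only if these genes keep rising past 72 h, a time that was not sampled. The lower level is also the result to be explained, so it is not a separate test. Across 13049 genes, which are not independent, the difference of ivd1-2 from WT at 72 h and the change from 24 to 72 h in hml1-2 had r = 0.129 and rho = 0.0818. A weaker abscisate response in ivd1-2 remains a candidate explanation that was not tested, with hormone levels not analysed here.

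MLO3, next to IVD in gene order, was lower in ivd1-2 in darkness only. Against WT its log2 was -0.221 at 0 h and 0.201 in 72 h of light, where WT was at 4.084 and 4.302 CPM. The same stock difference as for ILA is excluded, since hml1-2 had log2 0.251 against WT where ivd1-2 had -4.81. A lesion that spans the IVD neighbourhood may reduce both genes, though at 0 h and in 72 h of light only IVD was lower. Of 10 neighbours 2 were called, MLO3 and AT3G45260, against 16.5% of all genes (Fisher's exact test p = 0.674, two-sided), which does not decide it, since a lesion at the border of IVD and MLO3 would touch few genes.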
